A study of Mus musculus with 28 samples.

How the data were processed

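RNA was measured by sequencing in the dorsal lateral geniculate nucleus (dLGN), the thalamic nucleus that relays retinal input to visual cortex, of C57BL/6J mice of both sexes. There were 7 ages (embryonic day 18, E18, and postnatal days 4, 10, 16, 20, 27 and 32), with 4 mice per age and 28 libraries in all. Per the labels' protocols, the nucleus was dissected from vibratome slices, total RNA was depleted of ribosomal RNA, and libraries were sequenced on a NextSeq 500. The labels describe the 4 mice of an age as independent samples. All 4 E18 libraries and P27 library 5 held reads of both Xist and Y-linked genes, and whether a library held tissue of more than 1 animal is not given in the sources used here, so n counts libraries.

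The authors deposited 12 tables, a pair for each comparison of adjacent ages, with genes that went up in one and genes that went down in the other. Read counts per gene and library in the deposited tables were whole numbers and were used as they stand. The authors' fold change is a ratio of the later to the earlier age, and the p-value and its adjusted form in the deposited tables were used only where the authors' deposited table is named. The submitters' processing notes name BWA, edgeR 3.14.0 and the GRCm38 (mm10) build. The counting tool, the gene annotation and the use of strand are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The globin, histone and ribosomal protein families may share reads between near-identical copies. Each listed gene held at least 4 reads summed over the 8 libraries of its comparison. A further 96 columns of per-sample read density were not used. Gene symbols of 25 gene IDs had been turned into dates and 2 carried a copy suffix. The symbol of 25 of the former and 1 of the latter (Aqp4) was recovered through the gene ID in a RefSeq table of GRCm38. The astrocyte list gained Aqp4 by this repair, which was made after results had been seen. Coordinates are those of the deposited tables. Their starts equalled the 1-based starts of the RefSeq table for 12969 of 24139 matched genes, were 1 less for 219 and differed otherwise for 10951. They are taken as counted from 1.

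Library totals ran from 8224851 reads (P10 library 4) to 40206549 (P27 library 5). A floor of 3 counts corresponded to between 0.0746 and 0.365 CPM, the count scaled to the library total. Intervals and floors cover counting error only. Libraries are named by age and by the number in the column name (3 to 6), because the labels' replicate numbers could not be matched to columns. Within each age, the chi-square of counts between libraries was at least 27.29 per degree of freedom over the 6 pairs of any age, so no library repeated another within sampling noise.

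Each pair of adjacent ages was tested with edgeR 4.0.16 in R 4.3.3 on its 8 libraries: filterByExpr, TMM normalization, and the quasi-likelihood F test (glmQLFit, glmQLFTest), two-sided, with Benjamini-Hochberg adjustment. Genes with an adjusted p under 0.05 were called. No fit held a term for sex, and the sex make-up of the libraries differed between ages. Levels are TMM-scaled CPM of the 8 libraries compared, as mean ± SD with n = 4 per age, so the same age can show slightly different levels in its 2 comparisons. Levels of single libraries are CPM with all 28 libraries scaled together. Log2 fold changes are later over earlier age, with their standard errors (SE). Of 27 gene lists, 26 were tested with camera (limma 3.58.1, preset correlation 0.01, Benjamini-Hochberg over the lists) and the sex-linked list was only described. Camera with an estimated correlation and fry stand beside it. Members are counted as passing over all genes tested, and "adjusted over the list alone" where stated.

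The tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 5 rises and 5 falls of largest log2 fold change among called genes with a mean of at least 5 CPM and no overlap between ages, passing over predicted-gene names. It also took up to 4 leading members of each called list and up to 2 called members of opposite direction, Tnfrsf12a and Tnfsf12, and Grin2a, Grin2b, Gabra2, Slc12a5 and Slc12a2. Some genes that the rule took are not reported here, though they stay in the tests and list counts. Values of a selection of these are given, with the rest summarised by list.

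Alternatives included scaling factors by relative log expression, the method of the DESeq2 size factors, computed by edgeR in the same test. These are named DESeq2 size factors below. Others were the DESeq2 1.42.0 Wald test, limma-voom, no filter on low counts and 1 fit of all 28 libraries. The rest were each library left out in turn, a log2 fold change of at least 1, and the authors' deposited adjusted p. Total-count scaling and a block on the column number were added after seeing the data. Deviations from the age mean correlated between same-numbered columns of adjacent ages at 0.345, 0.641, 0.368 and 0.395 for P4 and E18 and at 0.32, 0.43, 0.144 and 0.194 for P10 and P4. In the 4 later comparisons columns 3, 4 and 5 gave 0.183 to 0.492, each correlating best with its own number, and column 6 gave 0.035, -0.095, -0.136 and 0.033. The column numbers were therefore taken to pair libraries only in the first pair of comparisons. The pairing is a hint from the data and the column names, not from the labels.

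The test was checked on simulated counts with 200 changed genes, besides a small changed list. The simulated genes varied independently of each other, without the correlation between genes or the structure other than age seen in the real libraries. The recovered shares may therefore not hold for the real counts. It recovered 27% of changes of 2-fold and 81% of 4-fold for P4 against E18 (18493 genes), and 22% and 80% for P20 against P16 (17615 genes), where 10.7% of calls were unchanged genes. For P32 against P27 (17262 genes) it recovered 22% and 71%.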

Results

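Gene expression was followed in the mouse dLGN over 7 ages, E18, P4, P10, P16, P20, P27 and P32, with 4 libraries per age, in a series on Fn14 (Tnfrsf12a, the receptor of the cytokine TWEAK, encoded by Tnfsf12). The design compares adjacent ages. Library totals ran from 8224851 to 40206549 reads, and 16938 to 24149 genes were detected per library. The share of reads from the mitochondrial chromosome ran from 1.37% to 21.81%. The largest changes named are those among called genes with a mean of at least 5 CPM and no overlap between the ages.

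**Figure D1:**
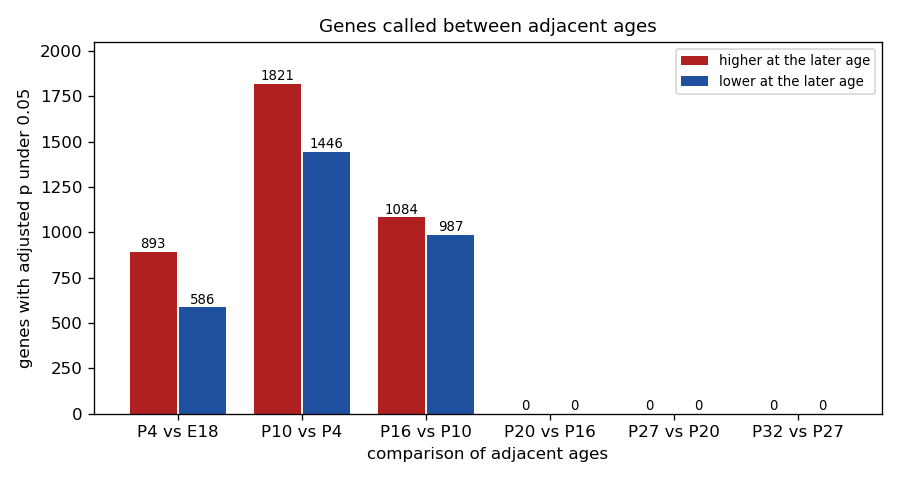
Genes with an adjusted p under 0.05 (vertical axis, number of genes) in each comparison of adjacent ages (horizontal axis), edgeR quasi-likelihood test, with bars for genes higher and lower at the later age. The first 3 comparisons called 1479, 3267 and 2071 genes, and each of the last 3 called 0.

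From E18 to P4, glial genes rose. Gfap, the intermediate filament of astrocytes (gene ID 14580, chromosome 11, 102887336 to 102897433, GRCm38), rose from 3.10 ± 1.55 to 124 ± 37.5 CPM (mean ± SD, n = 4 per age), a log2 fold change of 5.29 (SE 0.38). The other largest rises were Agt, encoding angiotensinogen (4.66, SE 0.34), Ppm1j (4.42, SE 0.89), Gpr37l1 (4.13, SE 0.27) and Aqp4, the astrocyte water channel (4.08, SE 0.65). Of 26 measured astrocyte genes, 21 rose and 5 did not pass (23 adjusted over the list alone), with a median log2 fold change of 1.62. Among them were Aldh1l1, which went from 29.0 ± 7.17 to 106 ± 10.9 CPM, and the glutamate transporter Slc1a3. Of 15 oligodendrocyte precursor genes, 12 rose (14 adjusted over the list alone), with Gpr17 at 5.09-fold and Pdgfra and Sox10 at log2 fold changes of 1.34 and 1.83.

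Microglial genes rose in 12 of 22 cases (16 adjusted over the list alone), including the receptors Csf1r (13.2 ± 1.73 to 35.6 ± 2.42 CPM), Cx3cr1 and P2ry12. Of 17 perineuronal net and matrix genes, 6 rose (11 and 1 falling adjusted over the list alone), led by Bcan, which encodes brevican (44.0 ± 8.35 to 230 ± 30.2 CPM), and with Acan, aggrecan, at 2.10 (adjusted p = 0.05 without E18 library 6). Red blood cell genes fell in 5 of 7 cases (6 adjusted over the list alone), with the globin gene Hbb-bs going from 271 ± 104 to 28.8 ± 7.36 CPM and Hba-a1 from 87.9 ± 62.7 to 10.2 ± 4.20 CPM. With an estimated correlation these 5 lists kept an adjusted p of 0.00505 (astrocyte), 0.0102 (oligodendrocyte precursor), 0.0408 (microglia), 0.0325 (perineuronal net and matrix) and 0.0325 (red blood cell).

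Of 29 synaptic vesicle and release genes 10 rose (18 adjusted over the list alone; adjusted p = 0.0837 with an estimated correlation), among them Sv2b (39.0 ± 6.82 to 141 ± 18.2 CPM) and Vamp1. Of 37 voltage-gated ion channel genes 11 rose and 1 fell (18 and 1 adjusted over the list alone; adjusted p = 0.158 with an estimated correlation). The potassium channel gene Kcna1 rose by 2.62 on the log2 scale, while Scn4b fell by 2.20. Scn4b did not pass without E18 libraries 5 or 6 or P4 libraries 5 or 6 (highest adjusted p = 0.124). Of 20 relay neuron genes 5 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.158 with an estimated correlation). The vesicular glutamate transporter genes Slc17a7 (9.19-fold) and Slc17a6 (1.77-fold) rose, and Zic1 fell from 1049 ± 145 to 670 ± 103 CPM. Zic1 did not pass without any 1 library other than E18 library 4 (highest adjusted p = 0.143, without E18 library 6). Of 25 immature neuron and progenitor genes 4 fell and 1 rose (7 and 2 adjusted over the list alone; adjusted p = 0.177 with an estimated correlation). Igf2bp1 fell from 22.4 ± 3.77 to 3.62 ± 0.81 CPM and Sox11 from 1021 ± 185 to 476 ± 69.3 CPM, while the radial glial gene Fabp7 rose by 1.39 on the log2 scale. Fabp7 did not pass without E18 library 5, E18 library 6 or P4 library 6 (adjusted p = 0.0564, 0.0662 and 0.055). In the cortex and hippocampus list (4 of 15 fell, 2 rose; 5 and 2 adjusted over the list alone; adjusted p = 0.158 with an estimated correlation), Tbr1 fell from 17.4 ± 5.82 to 3.50 ± 0.98 CPM and Nrgn rose by 1.57 on the log2 scale. That list was not called with the block on the column number (adjusted p = 0.0563) or without P4 library 6 (adjusted p = 0.0719).

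Of 24 myelinating oligodendrocyte genes 6 rose (6 adjusted over the list alone; adjusted p = 0.0741 with an estimated correlation), and of 25 refinement and immune-related genes 5 rose (6 adjusted over the list alone; adjusted p = 0.0837 with an estimated correlation). Of 26 activity-regulated genes 4 rose and 2 fell (9 and 3 adjusted over the list alone; adjusted p = 0.321 with an estimated correlation). Single members rose in the cell cycle (29 genes), ionotropic glutamate receptor (27 genes) and GABA-A receptor (14 genes) lists, with 0, 1 and 2 adjusted over the list alone and an adjusted p of 0.16, 0.338 and 0.338 with an estimated correlation. Imprinted growth genes fell in 4 of 18 cases (5 and 2 rising adjusted over the list alone; adjusted p = 0.218 with an estimated correlation, and 0.0536 by camera without P4 library 6). Cholesterol synthesis genes fell in 1 of 23 (1 adjusted over the list alone; adjusted p = 0.513 with an estimated correlation, and 0.0723 by camera without P4 library 3). None of 79 cytosolic ribosomal protein genes passed (0 adjusted over the list alone; adjusted p = 0.766 with an estimated correlation, and 0.78 by camera without E18 library 4), and 25 fell with the block. The histone list (adjusted p = 0.0895) was called with the block (adjusted p = 0.0141) and without E18 library 3, 4, 5 or 6 or P4 library 4 (adjusted p = 8.06e-06 to 0.0143), upward without E18 library 4 and downward in the others. Gabra2, a GABA-A receptor subunit gene, was at 124 ± 41.0 and 169 ± 52.3 CPM and did not pass (adjusted p = 0.393), but did with the block (adjusted p = 0.0121).

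The largest falls were Y-linked genes and Ttr. Eif2s3y (chromosome Y, 1010578 to 1035006) had 1617 reads over the E18 libraries and 0 over the P4 libraries, at least 410-fold lower against a floor of 3 counts over the group. Ddx3y had 2023 and 2 reads, a ratio of 769 (95% counting interval 212 to 6350), Uty had 1864 and 2 reads, a ratio of 708 (196 to 5850), and Kdm5d was at 31.5 ± 9.24 and 0.036 ± 0.072 CPM. With all 28 libraries scaled together, all 4 E18 libraries held reads of both Xist (251 to 769 CPM) and Ddx3y (9.18 to 21.7 CPM), whereas at P4 all 4 held Xist (763 to 1466 CPM) with Ddx3y at no more than 0.121 CPM. Xist is expressed in females and Ddx3y lies on the Y chromosome, so the falls of Y-linked genes go with the sex make-up of the libraries. P10 libraries 4 and 6 held Ddx3y at 30.4 and 57.0 CPM, with Xist at 5.77 and 9.05 CPM. P10 libraries 3 and 5 held it at 0.160 and 0 CPM, with Xist at 2499 and 1445 CPM. Kdm5d, Uty and Eif2s3y parted these libraries in the same way, which argues against a lasting fall of these genes with age. For other genes, sex make-up and age cannot be separated between E18 and P4. Ttr, the transthyretin gene made by choroid plexus epithelium (chromosome 18, 20665250 to 20674326), went from 446 ± 443 to 11.1 ± 8.75 CPM. With all 28 libraries scaled together, it stood at 949 CPM in E18 library 5, against 126 to 247 CPM in the other E18 libraries.

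In total 893 genes were higher and 586 lower at P4 among 18797 tested (edgeR, adjusted p under 0.05), and camera called 19 of 26 lists, 5 of them with an estimated correlation. Fry called 16 of the 26. Counts of higher genes were 405, 504 and 541 without E18 library 5, E18 library 6 and P4 library 6, and of lower genes 369 and 355 without E18 library 5 and P4 library 6. A block on the column number, added after seeing the data, gave 2970 higher and 2558 lower. Total-count scaling, which moved the median of all genes to -0.12 from -0.02, gave 613 higher and 686 lower. With the block, more list members passed. Rising members numbered 19 for microglia, 22 for synaptic vesicle, 15 for refinement and immune-related, 9 for ionotropic glutamate receptor and 7 for GABA-A receptor genes. Members that rose and fell numbered 22 and 2 for ion channel, 12 and 1 for cell cycle, 11 and 3 for activity-regulated, 10 and 2 for perineuronal net, 9 and 1 for myelinating oligodendrocyte and 8 and 1 for relay neuron genes. They numbered 2 and 14 for immature neuron and 3 and 9 for imprinted genes, while 8 cholesterol synthesis and 13 histone genes fell.

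From P4 to P10, myelin and astrocyte genes rose. Mobp (gene ID 17433, chromosome 9, 120149690 to 120181329), a myelin protein gene, rose from 1.90 ± 2.18 to 163 ± 19.2 CPM (mean ± SD, n = 4 per age; log2 fold change 6.59, SE 0.71). Other large rises were those of Myoc (5.37, SE 0.53), the sodium channel subunit gene Scn4b (5.05, SE 0.55) and Adra1d (4.88, SE 0.32). Of 25 myelinating oligodendrocyte genes 18 rose and 7 did not pass (20 adjusted over the list alone), with a median of 2.50. Mbp, myelin basic protein, rose from 47.2 ± 7.03 to 1065 ± 114 CPM and Mag from 6.41 ± 2.26 to 109 ± 21.6 CPM. Astrocyte genes rose in 21 of 26 cases (23 adjusted over the list alone), with the potassium channel gene Kcnj10 going from 35.4 ± 4.66 to 406 ± 33.4 CPM and the glutamate transporter gene Slc1a2 from 352 ± 81.0 to 1434 ± 107 CPM. Oligodendrocyte precursor genes rose in 11 of 15 cases (13 adjusted over the list alone), with Bcas1 at a log2 fold change of 3.15 (SE 0.20) and Gpr17 at 2.18 (SE 0.17).

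Of 37 voltage-gated ion channel genes 18 rose and 2 fell (23 and 2 adjusted over the list alone). Kcna1 rose from 28.9 ± 6.08 to 174.9 ± 17.98 CPM, and Scn3a, a sodium channel gene of the immature brain, fell by 0.67 on the log2 scale (adjusted p = 0.0501 and 0.0657 without P10 libraries 4 and 6). Of 25 immature neuron and progenitor genes 16 fell and 9 did not pass (16 adjusted over the list alone). Dcx, doublecortin, fell from 1037 ± 244 to 176 ± 44.2 CPM, Dpysl3 from 2713 ± 74.3 to 1099 ± 33.8 CPM and Tubb2b from 1413 ± 583 to 405 ± 69.8 CPM. These 5 lists kept adjusted p values with an estimated correlation of 0.00583 (myelinating oligodendrocyte), 0.0023 (astrocyte), 0.00311 (oligodendrocyte precursor), 0.0371 (ion channel) and 0.0219 (immature neuron).

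Other lists lost their call with an estimated correlation, while fry called 13 of the 26 lists in this comparison. Of 29 cell cycle genes 10 fell and 1 rose (14 and 1 adjusted over the list alone; adjusted p = 0.0553 with an estimated correlation). The replication gene Mcm6 went from 32.7 ± 3.79 to 16.7 ± 2.57 CPM and cyclin D1 (Ccnd1) rose by 0.71 on the log2 scale. Of 39 axon guidance genes 14 fell and 5 rose (18 and 5 adjusted over the list alone; adjusted p = 0.0699 with an estimated correlation), with the ephrin gene Efnb3 falling by 1.43 and the semaphorin gene Sema5a rising by 1.55 on the log2 scale. Of 29 synaptic vesicle genes 11 rose and 1 fell (12 and 2 adjusted over the list alone; adjusted p = 0.119 with an estimated correlation). Snap25 went from 156 ± 19.9 to 353 ± 52.8 CPM, and Syn3 fell by 1.12. Of 27 activity-regulated genes 11 rose and 1 fell (11 and 1 adjusted over the list alone; adjusted p = 0.263 with an estimated correlation), with Vgf rising by 1.90 and the neurotrophin gene Bdnf falling by 1.31. Endothelial and pericyte genes rose in 6 of 20 cases (13 adjusted over the list alone; adjusted p = 0.428 with an estimated correlation), among them Slco1a4. Cholesterol synthesis genes fell in 7 of 23 cases (7 and 1 rising adjusted over the list alone; adjusted p = 0.453 with an estimated correlation), among them Fdft1. Of 22 microglial genes 7 rose (12 adjusted over the list alone; adjusted p = 0.263 with an estimated correlation). Of 6 red blood cell genes 1 rose (3 adjusted over the list alone; adjusted p = 0.428 with an estimated correlation, and 0.065 by camera without P4 library 6). Of 53 replication-dependent histone genes 5 fell (0 adjusted over the list alone; adjusted p = 0.521 with an estimated correlation), and of 76 cytosolic ribosomal protein genes 4 fell and 1 rose (3 and 0 adjusted over the list alone; adjusted p = 0.454 with an estimated correlation). The relay neuron, refinement and immune-related, and mitochondrially encoded lists (adjusted p = 0.0609, 0.0589 and 0.259) were called with the block on the column number (adjusted p = 0.0488, 0.015 and 0.00509). Each was also called without at least 1 library (lowest adjusted p = 0.00661, 0.0101 and 0.00424, without P10 library 5, P4 library 4 and P4 library 4), and the relay neuron and refinement lists with no filter or with total-count scaling. Without P10 library 5 camera also called the inhibitory neuron list, as lower (adjusted p = 0.000751, against 0.575 with all libraries).

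The largest falls were Krt19, a keratin gene (log2 fold change -5.72, SE 0.80), Isl1 (-4.59, SE 0.95), Fgf10 (-4.55, SE 0.61), the neuropeptide gene Npy (-4.32, SE 0.44) and Pvalb, encoding parvalbumin, at 9.93 ± 4.94 and 0.56 ± 0.19 CPM. The NMDA receptor subunit gene Grin2a rose from 15.8 ± 4.12 to 30.3 ± 12.4 CPM (adjusted p = 0.0383) and Grin2b was at 643 ± 59.0 and 722 ± 121 CPM (adjusted p = 0.495). The chloride transporter genes Slc12a5 and Slc12a2 rose by 0.69 and 0.68 on the log2 scale. Grin2a did not pass without P4 libraries 3, 4 or 6 or P10 libraries 3 or 5 (adjusted p up to 0.104), nor Slc12a2 without P4 library 6 or P10 libraries 3 or 6 (up to 0.0876).

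In total 1821 genes were higher and 1446 lower at P10 among 17717 tested, and camera called 15 of 26 lists. Lower genes numbered 927 and 819 without P4 library 6 and P10 library 6. The block on the column number gave 3196 higher and 3212 lower, and total-count scaling gave 1357 higher and 1695 lower. With the block, 45 ribosomal protein genes fell and 1 rose, and 28 histone and 17 cell cycle genes fell, the latter with 1 that rose. Rising members numbered 13 for microglia, 13 for endothelial cell and pericyte, 5 for red blood cell and 6 of 7 for mitochondrially encoded genes. Members that rose and fell numbered 18 and 2 for synaptic vesicle, 23 and 4 for ion channel, 9 and 4 for relay neuron and 1 and 12 for cholesterol synthesis genes.

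From P10 to P16, all 26 measured myelinating oligodendrocyte genes rose (26 adjusted over the list alone), with a median log2 fold change of 3.34 (adjusted p = 0.0171 with an estimated correlation). Mal went from 8.83 ± 2.69 to 658 ± 278 CPM (mean ± SD, n = 4 per age) and Mog, a myelin surface glycoprotein gene, from 21.9 ± 3.58 to 343 ± 101 CPM. The largest rises were Etnppl (gene ID 71760, chromosome 3, 130617448 to 130635750; 7.09, SE 0.31), Mal, Opalin (6.01, SE 0.44), Prkcd, a protein kinase C gene (19.1 ± 7.16 to 754 ± 374 CPM), and Ermn (5.13, SE 0.39). Of 26 astrocyte genes 10 rose and 16 did not pass (13 and 1 falling adjusted over the list alone; adjusted p = 0.0293 with an estimated correlation), among them Aldoc (154 ± 19.5 to 480 ± 71.1 CPM) and glutamine synthetase, Glul (313 ± 16.6 to 773 ± 106 CPM).

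Of 29 cell cycle genes 21 fell (24 adjusted over the list alone; adjusted p = 0.0293 with an estimated correlation). The proliferation marker gene Mki67 went from 41.2 ± 6.46 to 9.10 ± 4.23 CPM and Rrm2 from 11.6 ± 0.87 to 3.41 ± 0.44 CPM. Of 24 immature neuron and progenitor genes 14 fell (17 adjusted over the list alone; adjusted p = 0.0293 with an estimated correlation). Fabp7 went from 306 ± 37.1 to 51.3 ± 10.4 CPM and Dcx from 165 ± 40.6 to 44.5 ± 8.92 CPM. Of 50 replication-dependent histone genes 18 fell and 2 rose (29 and 3 adjusted over the list alone; adjusted p = 0.405 with an estimated correlation). Hist1h1b fell by 2.59 and Hist2h3c1 rose by 2.56 on the log2 scale. Slc6a4, the serotonin transporter gene (chromosome 11, 76998466 to 77032345), fell from 22.3 ± 5.88 to 0.18 ± 0.17 CPM. The other largest falls were Rtn4rl2 (-3.18, SE 0.69), St8sia2 (-3.12, SE 0.58), the histidine decarboxylase gene Hdc (48.8 ± 6.97 to 6.41 ± 4.32 CPM) and Ryr1 (-2.83, SE 0.44).

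Of 27 ionotropic glutamate receptor genes 6 rose and 4 fell (8 and 4 adjusted over the list alone), and of 15 GABA-A receptor and chloride transport genes 5 rose and 5 fell (5 and 5 adjusted over the list alone). Neither list was called (camera adjusted p = 0.714 and 0.762). Gabra2 fell from 120 ± 26.1 to 46.8 ± 15.3 CPM. Grin2a rose from 28.3 ± 11.5 to 119 ± 22.2 CPM (adjusted p = 0.000377) and Grin2b was at 677 ± 116 and 884 ± 304 CPM (adjusted p = 0.445). Slc12a2 rose from 98.8 ± 17.7 to 310 ± 94.1 CPM and Slc12a5 was at 512 ± 69.7 and 475 ± 107 CPM (adjusted p = 0.808). Of 27 activity-regulated genes 6 rose (9 and 1 falling adjusted over the list alone; adjusted p = 0.514 with an estimated correlation), among them Fos (9.37 ± 0.087 to 26.6 ± 6.27 CPM) and Arc (5.81 ± 1.34 to 24.7 ± 13.7 CPM). Of 23 cholesterol synthesis genes 7 rose (12 and 1 falling adjusted over the list alone; adjusted p = 0.514 with an estimated correlation). Axon guidance genes fell in 9 and rose in 5 of 39 cases (11 and 6 adjusted over the list alone; adjusted p = 0.514 with an estimated correlation), with Robo2 falling by 1.29 and Efnb3 rising by 1.24. The axon guidance list was not called without P10 library 5, P16 library 4 or P16 library 5 (adjusted p = 0.0715, 0.056 and 0.0558). Of 29 synaptic vesicle genes 5 rose and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 0.633 with an estimated correlation), with Snap25 at 331 ± 50.8 and 817 ± 208 CPM and Stx1a falling by 2.02 (adjusted p of the list = 0.0968 by camera without P16 library 6). In the imprinted list (6 of 18 fell, 2 rose; 9 and 2 adjusted over the list alone; adjusted p = 0.514 with an estimated correlation) Magel2 fell by 1.67 and Peg3 rose by 0.78 on the log2 scale (adjusted p = 0.0761, 0.066 and 0.0879 without P10 libraries 4, 5 and 6).

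Of 22 microglial genes 3 rose (4 adjusted over the list alone; adjusted p = 0.633 with an estimated correlation), and the list was not called without P10 library 5, P10 library 6 or P16 library 5 (adjusted p = 0.0715, 0.0835 and 0.0592). Of 73 cytosolic ribosomal protein genes 1 fell (0 adjusted over the list alone; adjusted p = 0.633 with an estimated correlation). None of 75 oxidative phosphorylation genes passed (0 adjusted over the list alone; adjusted p = 0.847 with an estimated correlation), and the list was not called without P10 libraries 3 or 5 or P16 libraries 5 or 6 (highest adjusted p = 0.564).

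In total 1084 genes were higher and 987 lower at P16 among 17474 tested, and camera called 13 of 26 lists, 4 of them with an estimated correlation. Without P10 library 6 the counts were 686 and 588, lower genes numbered 609 without P16 library 5, and total-count scaling gave 798 higher and 1238 lower.

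**Figure D2:**
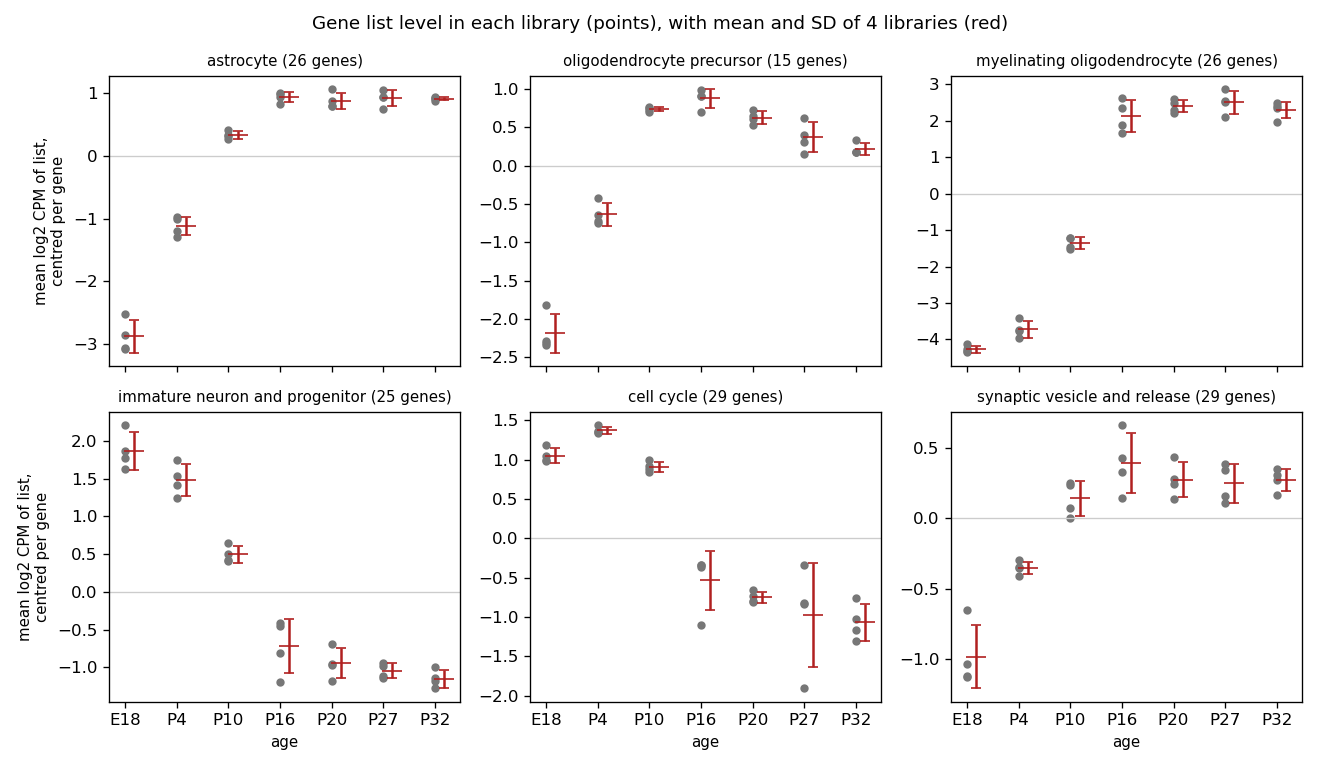
Mean log2 CPM of the genes of 6 lists, centred per gene over the 28 libraries (vertical axis), by age (horizontal axis), with grey points for libraries and red marks for the mean and SD of the 4 libraries of an age. The myelinating oligodendrocyte list climbs from P4 to P16 and the cell cycle and immature neuron lists descend from P4 to P16.

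From P16 to P20 no gene was called among 17949 tested with edgeR (485 at an unadjusted p under 0.05; 0 by DESeq2 and by limma-voom). Grin2a was at 113 ± 22.3 and 103 ± 13.5 CPM and Slc12a2 at 295 ± 90.8 and 310 ± 45.4 CPM (mean ± SD, n = 4 per age; adjusted p = 0.993 and 0.995). Camera called 11 of 26 lists, with no member past the test. The oligodendrocyte precursor list had a median log2 fold change of -0.21 (adjusted p = 0.361 with an estimated correlation) and the immature neuron list -0.35 (adjusted p = 0.626 with an estimated correlation). The other 9 lists lost the call without at least 1 library. They were inhibitory neuron (median 0.60), relay neuron (-0.34), myelinating oligodendrocyte (0.24), endothelial cell and pericyte (0.22), red blood cell (0.45), cell cycle (-0.10), synaptic vesicle (-0.17), cytosolic ribosomal protein (-0.14) and oxidative phosphorylation (-0.21), with an adjusted p between 0.361 and 0.627 with an estimated correlation. Without P20 library 3, camera gave an adjusted p of 0.059 for relay neuron, 0.0612 for inhibitory neuron, 0.232 for endothelial cell and 0.273 for both ribosomal protein and oxidative phosphorylation. Without P16 library 6 it gave 0.165 for myelinating oligodendrocyte and for synaptic vesicle, and without P16 library 5 it gave 0.546 for endothelial cell. Without P16 library 3 it gave 0.0571 for red blood cell and 0.218 for cell cycle. Mitochondrial reads took 4.27% to 13.01% of the P16 libraries and 4.46% to 19.66% of the P20 libraries. The authors' deposited table called 1 gene, Crygc, a lens crystallin gene, as lower at P20 (fold 0.00417, adjusted p = 0.0415). With all 28 libraries scaled together, Crygc stood at 17.9 CPM in P16 library 5 and at 1.61, 0.432 and 0 CPM in P16 libraries 3, 4 and 6.

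From P20 to P27 no gene was called among 18070 tested with edgeR (476 at an unadjusted p under 0.05; 7 by DESeq2, 5 higher and 2 lower, and 0 by limma-voom). Without P27 library 4 edgeR called 1. Serpinb1a, named after its values were seen, had the smallest adjusted p (0.0638, log2 fold change 2.83, SE 0.34), and the authors' deposited table called it with Pls1, Eps8l2 and Qdpr as higher and the somatostatin gene Sst as lower. Grin2a was at 101 ± 12.7 and 146 ± 31.1 CPM (mean ± SD, n = 4 per age; adjusted p = 0.929). Camera called 12 lists with no member past the test and 1 member falling adjusted over the list alone, in the inhibitory neuron list (median -0.77). The others with a call whichever library was left out were oxidative phosphorylation (median 0.28), cytosolic ribosomal protein (0.29), oligodendrocyte precursor (-0.24), endothelial cell and pericyte (-0.37), perineuronal net and matrix (-0.43) and imprinted growth (-0.27). All 7 had an adjusted p = 0.627 with an estimated correlation. Relay neuron (0.179 without P20 library 3), microglia (0.416 without P20 library 6), GABA-A receptor (0.0863 without P27 library 5), cholesterol synthesis (0.129 without P27 library 4) and histone (0.405 without P20 library 3) lost the call, and their adjusted p was 0.627 to 0.668 with an estimated correlation.

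From P27 to P32 no gene was called among 17856 tested with edgeR (73 at an unadjusted p under 0.05; 0 by DESeq2, by limma-voom and in the authors' deposited table). Grin2a was at 149 ± 30.6 and 192 ± 58.3 CPM (mean ± SD, n = 4 per age). Camera called 13 lists with no member past the test. Of these, cholesterol synthesis (median -0.29; adjusted p = 0.247 with an estimated correlation) and histone (median -0.26; adjusted p = 0.357 with an estimated correlation) were called whichever library was left out. Without P27 library 3, the adjusted p was 0.111 for myelinating oligodendrocyte (median -0.26), 0.11 for oligodendrocyte precursor (-0.17), 0.0578 for microglia (-0.13), 0.405 for cell cycle (-0.08) and 0.0533 for mitochondrially encoded genes (-0.61). Red blood cell (-0.74) stood at 0.0667 and immature neuron (-0.12) at 0.101 without P27 library 4, and ribosomal protein (-0.12) at 0.902 without P32 library 3. The inhibitory neuron list (0.26) was called in the other direction without P32 library 3 (adjusted p = 1.55e-05) and lost the call without P27 libraries 4 or 5 (0.095 and 0.0919). Its centred mean log2 level was 1.62 in P32 library 3 and -0.83 to -0.44 in the other P32 libraries. Without a call, meninges and choroid plexus (-0.29) turned direction without P27 library 4 (0.716), and oxidative phosphorylation (-0.12) without P27 library 6 or P32 library 3 (0.347 and 0.537). These 11 lists had an adjusted p of 0.247 to 0.948 with an estimated correlation. P27 library 6 detected 16938 genes, the fewest of the 28 libraries.

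Tnfrsf12a (gene ID 27279, chromosome 17, 23675445 to 23677449) and Tnfsf12 (gene ID 21944, chromosome 11, 69686240 to 69696098) did not pass the test on all 8 libraries in any of the 6 comparisons, although Tnfrsf12a passed from P4 to P10 and from P10 to P16 under other settings. With all 28 libraries scaled together, Tnfrsf12a stood at 1.06 ± 0.37 CPM at E18, 1.92 ± 1.42 at P4, 4.27 ± 1.69 at P10, 7.40 ± 2.20 at P16, 6.401 ± 3.76 at P20, 6.53 ± 2.91 at P27 and 12.5 ± 5.46 at P32 (mean ± SD, n = 4). Its adjusted p was lowest from P4 to P10 (0.0962, log2 fold change 1.20, SE 0.47), where the authors' deposited table gave a fold of 2.26 with an adjusted p of 0.0741. For P4 to P10 it passed with DESeq2 (adjusted p = 0.0487), with limma-voom (adjusted p = 0.034) and with the block on the column number (adjusted p = 0.0045). It also passed with edgeR without P4 library 4, whose level was 4.02 CPM (log2 fold change 1.78, adjusted p = 0.00792). Over all alternatives the adjusted p ran from 0.0045 to 0.221 and the log2 fold change from 0.95 to 1.78. From P10 to P16 its adjusted p was 0.153 (log2 fold change 0.81, SE 0.34), with 0.0493 without P16 library 3. Over all alternatives it ran from 0.0363 to 0.317. Means of Tnfsf12 lay between 1.65 CPM at P10 and 3.04 CPM at P27.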

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

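The tests below were chosen after the results were seen, except those of P32 against P16 and of the mitochondrial share.

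With edgeR as planned no gene was called between adjacent ages after P16 (485, 476 and 73 at an unadjusted p under 0.05). DESeq2 called 7 for P27 against P20, where the authors' deposited table called 5, with 1 for P20 against P16, and other settings called at most 1. Since each of the 35 splits of the 8 libraries reaches a count of 0, the splits say nothing about chance there. A split of P16 library 3 and P20 libraries 3, 4 and 6 from the other 4 called 4449 genes and a split of P20 libraries 3, 4 and 6 and P27 library 3 called 2823 (4 for P27 and P32), which points to a structure of the samples other than age. The first set held 13.01% to 19.66% mitochondrial reads and the rest 4.27% to 7.39%, and for P20 against P16 4174 genes followed that share (0 for P27 and P32). With the share in the fit the 3 comparisons still called 0 genes by age. That does not decide whether library differences that follow the share kept genes from being called. The share ran higher at P20 (4.46% to 19.66%) than at P16 (4.27% to 13.01%), so this fit can also take out change with age. For P27 against P20 and P32 against P27 0 genes followed the share, so including it could change little there. The same fit gave 1244 higher and 990 lower for P4 against E18, against 893 and 586 without the share. For P27 against P20, 0 genes were called without P27 library 6, with 320 at an unadjusted p under 0.05 against 476 with it. That does not decide whether 1 library of low complexity at P27 kept genes from being called. Leaving a library out also lowers the power of the test. If change were too slow for adjacent ages, P32 against P16 was to call at least 100 genes, and under 10 if not; edgeR called 35, which lies between, and from 1 (without P16 library 4, P16 library 6 or P32 library 6) to 66 (without P16 library 3), limma-voom called 39, and DESeq2 called 228, past the upper bound. Slow change and little change with age cannot be told apart, because the tools fall on different sides of that bound.

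Motile cilium genes were higher at E18 than P4. In a list written after the leading genes were seen, 31 of 35 fell by P4. The summed levels at E18 were 673, 665, 762.9 and 756.6 CPM, while a choroid plexus list that includes Ttr summed to 349.8, 455.6, 1177 and 422.6 CPM, so the ratio of the sums differed 2.97 times between libraries, but 1.32 times without E18 library 5. The ratio thus cannot tell choroid plexus tissue as the only source from other sources. The difference rests on 1 library, where Ttr alone stood at 949 of the 1177 CPM. The choroid plexus sum also need not follow that tissue. It was 455.6 CPM in both P4 library 3 and E18 library 4, with Ttr at 1.76 and 247 CPM. A difference in age, or in the tissue next to the nucleus, may also account for the higher motile cilium levels at E18 and was not tested.

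P27 library 6 detected the fewest genes although it held 31406305 reads, 21.81% of them mitochondrial. Its nuclear reads alone exceeded the 8224851 reads of the smallest library, which detected 21380 genes. That argues against lower depth and against reads taken up by mitochondrial transcripts before any thinning. Thinned to 8224851 reads it detected 16776, below the 18852 to 22441 of the other 27 libraries. Thinned to 7105311 nuclear reads it detected 16762, against 18795 to 22226. The lowest of the other libraries was P32 library 6 in both (18852 and 18795), also apart from the rest. At 8224851 reads the next lowest was P16 library 4, with 20638. The thinning gives the size of the gap and was no further test of these explanations. Fewer distinct molecules in P27 library 6 stays open and was not tested, and no biological explanation was tested.

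For the first 3 comparisons 1 of the 35 splits, the split by age, gave as many genes. It gave 1479 genes for P4 against E18, with 490 in the highest other split (libraries 3 and 5 of both ages from 4 and 6). For P10 against P4 it gave 3267, with 0 in the highest other split, and for P16 against P10 2071, with 2. For P16 against P10 that share of the splits is under 0.05, which would argue against chance only if no libraries were paired. Columns 3, 4 and 5 correlated best with their own number there (0.319, 0.204 and 0.183), though column 6 did not (0.035). The splits therefore do not decide about chance for P16 against P10. Where the column numbers pair the libraries, for P4 against E18 and P10 against P4, 8 splits part all 4 pairs. These are too few for a share under 0.05, so the splits cannot exclude chance there. The 7 other than the split by age called 0 genes. The split with 490 genes keeps the pairs together, so it follows the column number.

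In 24 of 260 groups of 4 libraries, 1 library stood far from the other 3, and chance gives about 1 in 20. Besides P27 library 6, P4 library 3 detected 22230 genes at 1 depth. At E18 these were Aldh1l1 (35.4 CPM), Aqp4 (32.7) and Gpr17 (21.0) in library 3 and Ttr (949) in library 5. At P4 they were Tnfrsf12a (4.02), Tnfsf12 (4.31) and Tubb2b (2130) in library 4, Isl1 (5.99, lowest) and Myoc (1.82) in library 3, Ddx3y (0.121) in library 5, and Kdm5d (0.128) and Uty (0.0638) in library 6. For Ddx3y, Kdm5d and Uty the other P4 libraries held no read, so a few reads near the floor were enough to set the flag. At P10 they were Isl1 (3.08) and Mbp (850, lowest) in library 5 and Npy (1.70) and Tubb2b (481) in library 4. At P16 they were Aldoc (602) in library 5 and Peg3 (991) and Slc12a2 (457) in library 3. Grin2b was lowest in library 3 at P27 (607) and P32 (532), and Tnfrsf12a was highest in P27 library 5 (10.9).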

How the results depend on the processing

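Total-count scaling and the block on the column number were chosen after seeing the data. The planned block on the labels' replicate numbers was not run, because these could not be matched to the columns; pseudocount settings do not apply to counts. With the replicate block by column number, genes higher and lower were 2970 and 2558 for P4 against E18, 3196 and 3212 for P10 against P4, 1725 and 1674 for P16 against P10, and 1 and 0 for P20 against P16. After P10 column 6 did not correlate with its own number over 0.1, although columns 3, 4 and 5 did, so the numbers were not taken as pairs. There the block also called the inhibitory neuron (adjusted p = 0.016) and refinement and immune-related (0.0253) lists and Tnfrsf12a (0.0363) for P16, mitochondrially encoded genes (0.00154) for P20, red blood cell (0.03) for P27 and relay neuron (0.00158) for P32, but not microglia (0.0638) for P27 nor inhibitory neuron (0.68) and cell cycle (0.0762) for P32. A log2 fold change of at least 1 left 569 higher and 455 lower for P4, 1025 and 608 for P10, and 650 and 658 for P16. The DESeq2 Wald test gave 1324 higher and 965 lower for P4, 2203 and 1996 for P10, and 1512 and 1372 for P16. For P27 it gave 5 and 2. The fit of all 28 libraries gave 916 higher and 354 lower for P4, 1473 and 953 for P10, and 1300 and 935 for P16. For P27 that fit gave 1 higher. For P27, no filter and total-count scaling each gave 1 higher, and the authors' deposited table gave 4 higher and 1 lower. That source gave 1 lower for P20. The causes were not tested.

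With an estimated correlation, called lists went from 19 to 5, 15 to 5, 13 to 4, and 11, 12 and 13 to 0, in order of age. Fry called 16 for P4 against E18, 13 for P10 against P4, 6 for P16 against P10 and 0 in the last 3. Leaving out 1 library gave 405 to 860 higher and 355 to 568 lower for P4, 1260 to 1783 and 819 to 1404 for P10, 686 to 1329 and 588 to 1180 for P16, 0 to 0 for P20 and P32, and 0 to 1 higher and 0 lower for P27. Called lists then ranged over 17 to 22, 14 to 18, 11 to 16, 7 to 17, 11 to 14 and 8 to 13, and of 7, 11, 13, 15, 14 and 13 lists without a call 5, 8, 5, 12, 6 and 4 gained one without at least 1 library.

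Over single reported genes, leaving out 1 library kept direction and side of the threshold in 3026 values, ended a call in 188 and gained one in 16; over lists with a call, 595 values kept it and 65 lost it. Directions turned in genes that had not passed and in 3 lists with a call. Some lists without a call were called in the other direction, as the histone list for P4 against E18. Oxidative phosphorylation was called downward there without P4 library 4 (camera adjusted p = 0.0166) and upward without E18 library 4 (camera adjusted p = 1.58e-05). For P32 against P27 without P32 library 3, camera called relay neuron upward (0.0309) and axon guidance (0.0252) and imprinted growth (0.00154) downward. Ranges with 1 library left out, on the log2 scale, were for P4 against E18 Tnfsf12 -0.029 to 0.527, Grin2a -0.019 to 0.258 and Slc12a2 -0.085 to 0.208 (-0.023 with total counts); for P16 Slc12a5 -0.225 to 0.003; for P20 Tnfsf12 -0.043 to 0.622, Gabra2 -0.374 to 0.005 and Slc12a2 -0.017 to 0.331; for P27 Tnfrsf12a -0.346 to 0.484, Gabra2 -0.265 to 0.168, Slc12a2 -0.192 to 0.192 and Slc12a5 -0.125 to 0.092 (-0.006 with DESeq2 size factors, the Wald test and the block, -0.005 with limma-voom). For P32 they were Sst -0.36 to 2.07, Gad1 -0.52 to 1.31, Ndufa3 -0.60 to 0.004, Tnfsf12 -0.41 to 0.013, Gabra2 -0.32 to 0.24 (-0.017 with limma-voom), Grin2b -0.084 to 0.295 and Slc12a2 -0.12 to 0.25. The P32 list tests of inhibitory neuron, meninges and choroid plexus, and oxidative phosphorylation turned, with adjusted p of 4.42e-06 to 0.095 (1.55e-05 for a call in the other direction without P32 library 3), 7.55e-09 to 0.716 and 1.66e-14 to 0.537.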

Other observations

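The lists of this part were written after the leading genes of the comparisons were seen, and the P32 against P16 test was set down before its result was seen.

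Motile cilium genes fell from E18 to P4 in 31 of 35 measured cases (34 adjusted over the list alone), with a median log2 fold change of -2.37 (camera adjusted p = 3.26e-38; adjusted p = 0.000512 with an estimated correlation). Among them were Hydin, a component of the ciliary axoneme (-3.64, SE 0.26), the axonemal dynein genes Dnah6 (-3.86, SE 0.38) and Dnah1 (-2.03, SE 0.20), and Foxj1, the transcription factor of motile cilia (-3.28, SE 0.39). From P4 to P10 a further 12 of 32 fell (13 adjusted over the list alone; adjusted p = 0.26 with an estimated correlation), and from P16 to P20 camera called the list as higher with no member past the test (adjusted p = 0.0405; 0.324 with an estimated correlation). Of 14 choroid plexus epithelium genes 7 fell from E18 to P4 (9 falling and 1 rising adjusted over the list alone; adjusted p = 0.111 with an estimated correlation), among them Ttr, Clic6 and Folr1.

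Collagen genes moved both ways. From E18 to P4 3 of 44 rose (3 and 1 falling adjusted over the list alone; adjusted p = 0.43 with an estimated correlation). From P4 to P10 9 of 44 rose and 3 fell (12 and 3 adjusted over the list alone; adjusted p = 0.746 with an estimated correlation). Col25a1 had the smallest adjusted p (log2 fold change 1.92, SE 0.18), and Col24a1 rose more (2.87, SE 0.46). From P10 to P16 11 fell and 2 rose (13 and 2 adjusted over the list alone; adjusted p = 0.597 with an estimated correlation), with Col6a6 at -2.19 (SE 0.42) and Col20a1 at 1.44 (SE 0.22). With no member past the test, camera called the list as lower from P20 to P27 (median -0.46, adjusted p = 2.28e-07; 0.515 with an estimated correlation) and from P27 to P32 (median -0.06, adjusted p = 0.0111; 0.935 with an estimated correlation). None of 57 clustered protocadherin genes passed in any of the 6 comparisons. Camera called that list as higher from E18 to P4 and from P20 to P27 (adjusted p = 0.000175 and 0.0164) and as lower in the 3 comparisons from P4 to P20 (adjusted p = 0.0334, 0.00441 and 6.53e-13, the last with a median of -0.38). With an estimated correlation these stood at 0.296 to 0.746. Of 18 neuropeptide genes 3 rose from E18 to P4 (3 adjusted over the list alone; adjusted p = 0.487 with an estimated correlation). From P4 to P10 2 of 17 rose and 3 fell (3 and 4 adjusted over the list alone; adjusted p = 0.781 with an estimated correlation), with Npy at -4.32 (SE 0.44), Sst at -2.85 (SE 0.51) and Trh at -2.12 (SE 0.62). From P10 to P16 2 of 16 fell (2 adjusted over the list alone; adjusted p = 0.597 with an estimated correlation). From P20 to P27 none passed, and camera called the list as lower (adjusted p = 0.0164; 0.0694 with an estimated correlation).

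Between P16 and P32, 12 genes were higher and 23 lower at P32 among 17648 tested (edgeR; 228 by DESeq2, 39 by limma-voom). Serpinb1a (3.56, SE 0.31), Qdpr (1.78, SE 0.20) and Ndrg1 (1.32, SE 0.18) were higher, and Gpr17 (-1.64, SE 0.19), Neu4 (-1.21, SE 0.17) and Bmp4 (-1.55, SE 0.22) were lower. These genes were named after their values were seen. The total of 35 fell to 1 without P16 library 4, P16 library 6 or P32 library 6.

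P27 library 5 held reads of both Xist (325 CPM) and Ddx3y (53.3 CPM), as did all 4 E18 libraries, whereas in each of the remaining libraries Xist was at most 9.05 CPM or Ddx3y at most 0.964 CPM. Xist was that low in no P4 library and in P10 libraries 4 and 6. It was so in P16 libraries 3, 4 and 5, P20 library 3, P27 library 3 and P32 libraries 4 and 6. Sex make-up thus also differed for P10 against P4, P16 against P10, P20 against P16 and P32 against P27. For P27 against P20 it differed by P27 library 5, which held reads of both kinds. No fit held a term for sex.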
